A study of Mus musculus with 33 samples.

How the data were processed

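Tissue from the medial nucleus of the trapezoid body was taken from live brain slices of wild-type mice with a needle under a dissecting microscope, per the labels' protocols, which enriches for cells of this nucleus without isolating a cell type. The labels describe the animals as FVB, while their strain tag reads FVN. Each sample is a single mouse. RNA was extracted with the Absolutely RNA Nanoprep kit, its integrity was checked on a Bioanalyzer, and it was amplified with the WT-Ovation Pico system, converted to sense-strand cDNA with the Exon module and labelled with biotin, per the labels' protocols. Amplification from small amounts of RNA can add variation between arrays that is unrelated to age.

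The authors deposited log2 expression values for 16686 probe sets on 33 arrays, made with Partek 6.3 and RMA, with mm9 as the genome build, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes on a log2 scale, and the settings used are not given in the sources used here. Normalization assumes that most genes do not change, so a change that shifts many genes in the same direction, as between P6 and P14, depends on the scaling. Arrays give intensities, so a level cannot be compared between probe sets, and changes of dim genes are compressed. The median log2 value of an array averaged 4.947 at P0 and 5.069 at P14, and the upper quartile 6.724 and 6.928.

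Gene names came from the platform annotation, which pairs 14993 probe sets with a single symbol, 1019 with several and 674 with none. Genes were named only from probe sets with a single symbol. Of these, 14939 were found by Entrez number in RefSeq's gene table for GRCm38.p6 and took its symbol, and 54 kept the annotation's symbol. That table is of another assembly than mm9, so no coordinates are given. Of the 14857 genes, 135 had several probe sets, and for 11 of these the probe sets went in opposite directions in a comparison that called any of them. The brightest probe set stood for a gene in list tests.

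Ages were taken from the labels. Limma 3.58.1 in R 4.3.3 was fitted to the log2 values of all 33 arrays with a mean for each of the 7 ages. A moderated F test asked which probe sets differed at any age, and 7 contrasts compared P1 with P0, P2 with P1, P3 with P2, P4 with P3, P6 with P4, P14 with P6 and P6 with P0. The comparisons of P6 with P0 and of P14 with P6 were the main ones. All tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison and a threshold of 0.05 on the adjusted p. No filter on dim probe sets was used. SE is the moderated standard error of a log2 change.

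The tests were tried on simulated data in which every array had the real means of the earlier age, with independent noise of each probe set's real spread. In these data 100 of 16686 probe sets were changed by each of 2 sizes. Variation shared between probe sets, whose leading component held 24.9% of the real residual variance, was not simulated, so recovery and false calls on the real arrays may differ. For P6 against P0 the fit recovered 91% of changes of 1 log2 and 52% of changes of 0.5 log2, with 8 false calls. For P14 against P6 it recovered 89% and 41%, with 5 false calls. In the single-day steps it recovered 86% to 94% of changes of 1 log2 and 39% to 63% of changes of 0.5 log2, with 6 false calls each.

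The gene lists, the genes reported at every age, the rule for naming genes and the alternatives, except the 2 named below, were written before the data were examined. The rule named, for each main comparison, the 8 highest and 8 lowest changes among called genes whose 2 ages do not overlap in any mouse, and 4 of each for the other steps, leaving out predicted and unnamed genes. For each list described it named up to 4 members with the largest called changes, and for genes called in opposite directions before and after P6 the 5 in each order with the largest smaller change. The 32 lists cover principal neuron and glycinergic genes, potassium, sodium and calcium channels, glutamate and inhibitory receptors, synaptic vesicles, the active zone, neurite growth, axon guidance, BMP and TGF-beta signalling, extracellular matrix, collagens and laminins, the cell cycle, cholesterol synthesis, glycolysis, mitochondrial respiration, nodes of Ranvier, complement, immediate-early genes and markers of other cell types. Some genes stand in more than 1 list, such as Scn1a, Slc17a8, Aldoc, Slc2a1 and Bmp4. Lists of at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 32 lists and 7 comparisons. Of these 224 tests 59 were called, 43 higher and 16 lower, and 9 remained called with an estimated correlation. With the ages of all arrays shuffled, a median of 30 tests were called at the preset correlation, so a list call lost with an estimated correlation is weak evidence. Counts adjusted over the list alone are given where they differ from those over all probe sets.

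The titles number the litters, so mice with the same number are taken to be litter mates across ages. Residuals from the age means correlated weakly within litters, with a mean r of 0.0243, 0.148, 0.122, 0.2 and 0.0227 for litters 1 to 5 against -0.0216 between mice of different litters and ages, and the consensus correlation was 0.0989. The fit described here leaves litter out. With litter as a block 50 probe sets were called higher and 13 lower for P1 against P0, and this fit is given beside a result where it changes the call or moves a count by over 1.5 times.

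Other alternatives were litter as a random block, a fit of only the 2 ages compared, quantile normalization and centring of the deposited values, dropping the dimmest 25% of probe sets, an intensity trend with robust moderation, array quality weights, a further threshold of 1.5-fold, an adjusted p under 0.01, 1 probe set per gene, the mean of a gene's probe sets, an estimated correlation within lists, P6 mice split between comparisons, and leaving out each mouse in turn. Leaving out the 3 arrays of weight under 0.5 and adding the array spread as a covariate were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.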

Results

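The medial nucleus of the trapezoid body (MNTB) is a nucleus of the auditory brainstem. Its glycinergic principal neurons each receive a giant glutamatergic terminal, the calyx of Held, which forms in the days after birth. Gene expression was measured on arrays in MNTB tissue dissected from wild-type FVB mice at 7 postnatal ages. There were 5 mice each at P0, P1, P2, P3 and P6, and 4 mice each at P4 and P14, giving 33 arrays with 1 mouse per array. Each array carried 16686 probe sets, of which 14993 had a single gene symbol, and these named 14857 genes. Pearson correlations across probe sets between mice of the same age ranged from 0.9671 to 0.9904, and no pair of arrays held identical values. The number of arrays limits the precision of every comparison. The ages ask which transcripts of the dissected tissue change while the calyx forms, from P0 to P6, and which change later, from P6 to P14. No cell type was isolated, so a change cannot be assigned to principal neurons, to the calyx or to other cells.

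Many genes differed in level between the ages. Limma's F test across the 7 ages called 4761 of 16686 probe sets (28.5%) at an adjusted p under 0.05, and 2073 of these had age means spanning at least 1 log2 unit. The highest age mean lay at P14 for 2712 of the called probe sets, at P0 for 971 and at an age between these for 1078. These counts are on the deposited scale, on which array medians averaged 5.069 at P14 and 4.953 at P6. Of the calls between P6 and P14, 75.4% were higher at P14 as deposited and 51.2% after quantile normalization. The number of probe sets highest at P14 may therefore depend on the scaling. The first principal component held 37.7% of the variance and the second 13.3%. Mean scores on the first component ran in the order of age, from -24.24 ± 4.39 (SD, n = 5) at P0 through -6.88 ± 1.3 at P3 and 11.99 ± 4.88 at P6 to 65.97 ± 3.95 (SD, n = 4) at P14.

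**Figure D1:**
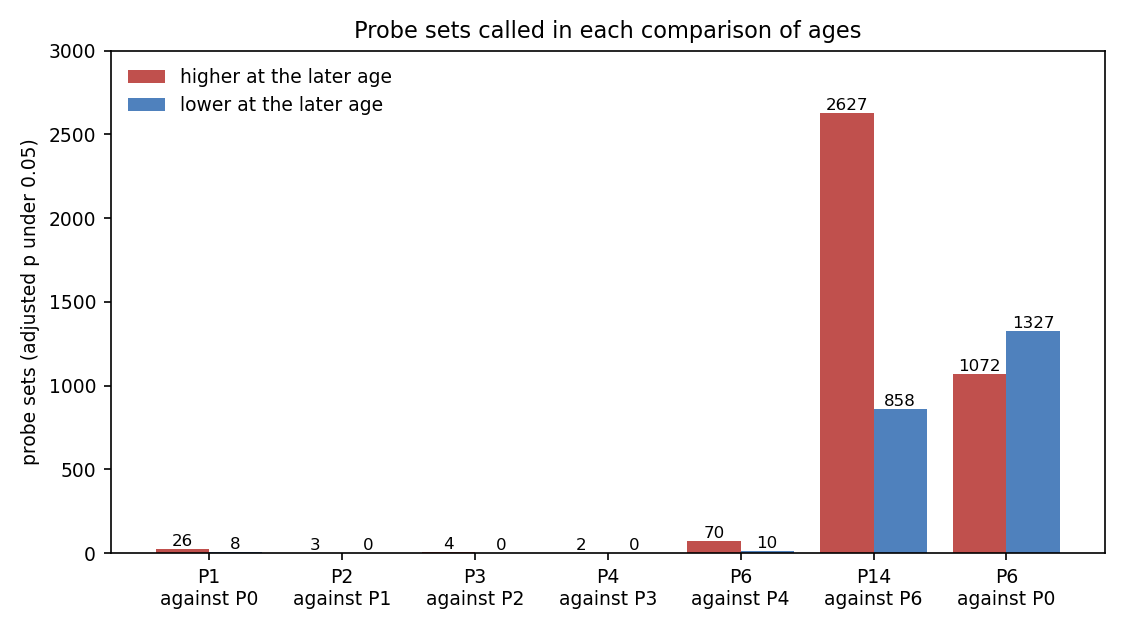
Number of probe sets called higher and lower at the later age in each 2-age comparison, at an adjusted p under 0.05 in limma. The comparison of P14 with P6 has the most calls (2627 higher, 858 lower), followed by P6 with P0 (1072 higher, 1327 lower), while the steps between P1 and P4 have 2 to 4 calls each.

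Of 22 measured genes chosen in advance for their known roles in this nucleus, 18 differed across the ages in the F test. The calcium-binding proteins Pvalb and Calb1, which mark principal neurons, had some of the widest ranges. Mean log2 Pvalb was 5.54 ± 0.19 (SD, n = 5) at P0, 8.36 ± 0.44 at P3, 10.4 ± 0.2 at P6 and 11.5 ± 0.23 (SD, n = 4) at P14. Mean log2 Calb1 went from 4.76 ± 0.43 at P0 to 7.01 ± 0.36 at P1, 9.99 ± 0.29 at P6 and 10.9 ± 0.18 at P14. Slc6a5, the glycine transporter of glycinergic terminals, was already bright at P0 (9.81 ± 0.14) and stood at 10.9 ± 0.23 at P6. The vesicular glutamate transporter Slc17a8 took the opposite course, from 8.04 ± 0.41 at P0 to 4.9 ± 0.36 at P3 and 4.25 ± 0.11 at P6. Doublecortin, Dcx, a microtubule protein of immature neurons, went from 10.7 ± 0.13 at P0 to 9.02 ± 0.3 at P3, 8.02 ± 0.33 at P6 and 6.34 ± 0.19 at P14. Syt1, a calcium sensor of vesicle release, had means between 10.8 and 11.1 up to P6 and 7.59 ± 0.49 at P14, while its relative Syt2 went from 6.54 ± 0.11 at P0 to 7.92 ± 0.4 at P6 and 8.5 ± 0.21 at P14. The glycine receptor subunit Glra1 was at 4.23 ± 0.34 at P0, 5.67 ± 0.58 at P6 and 9.27 ± 0.37 at P14, and the subunit Glra2 at 5.29 ± 0.33, 4.23 ± 0.18 and 3.52 ± 0.12. The F test did not call the AMPA receptor subunit Gria4 (adjusted p = 0.608), the chloride transporter Slc12a5 (adjusted p = 0.564) or the vesicular glutamate transporters Slc17a6 (adjusted p = 0.195) and Slc17a7 (adjusted p = 0.215). At every age Slc17a6 (means from 3.84 to 4.55) and Slc17a7 (from 3.7 to 4.35) lay under the median of their arrays, where changes are compressed.

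Over the first postnatal week, from P0 to P6, Calb1, Pvalb and several myelin genes were among the largest measured rises, and Slc17a8 and Dcx among the largest measured falls. Calb1 rose by 5.23 ± 0.191 (log2 change ± SE, 5 mice against 5; adjusted p = 9.38e-19). Mobp, a myelin protein, rose by 4.95 ± 0.16 (adjusted p = 8.83e-20) and Pvalb by 4.86 ± 0.2 (adjusted p = 1.32e-17), the latter 29.1-fold. The next largest rises among named genes were those of Mag (4.24), Ugt8a (4.18), Mbp (3.52), Chn2 (3.52) and Smpx (3.51). Slc17a8 fell by 3.79 ± 0.215 (adjusted p = 4.4e-14), the extracellular matrix gene of tenascin C, Tnc, fell by 2.95 ± 0.236 (adjusted p = 9.06e-11) and Dcx fell by 2.65 ± 0.154 (adjusted p = 6.55e-14). Crabp2 (-2.42), Dact1 (-2.24), the neuropeptide gene Sst (-2.07), Stk32b (-2.07) and Fxyd6 (-2.02) fell next. These 16 genes were chosen among called probe sets whose P0 and P6 mice do not overlap, which held for 1437 of the 2399 calls. By chance this would hold for 0.794% of all probe sets, but calls favour separated ages, so the shares are not comparable. All of these rises except that of Pvalb started at P0 from means under the median of their arrays, which averaged 4.947, namely Calb1 (4.76), Mobp (4.66), Mag (3.92), Ugt8a (4.91), Mbp (4.76), Chn2 (4.58) and Smpx (4.51). At P6, Slc17a8 (4.25), Crabp2 (4.15) and Stk32b (4.72) had means under the median of their arrays, which averaged 4.953. Changes of such dim probe sets are compressed, so no fold is given for them and their order is uncertain. In all, 1072 probe sets rose and 1327 fell (44.7% higher), 279 and 156 of them by at least 2-fold. The split turned to 1532 higher and 1226 lower with array quality weights, and without P6 litter 4 only 905 fell. Without the 3 arrays of lowest quality weight, an alternative chosen after seeing the data, it was 1289 and 1053 (55% higher).

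Among neuronal gene groups, more inhibitory receptor genes rose than fell between P0 and P6, and more voltage-gated calcium channel genes fell than rose. Of 14 measured inhibitory receptor and chloride transporter genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), among them the GABA-A receptor subunits Gabrb2 (1.56) and Gabra2 (1.36) and the glycine receptor subunits Glra1 (1.43) and Glrb (1.23). Camera called this list higher (adjusted p = 0.00138), a call lost with an estimated correlation (adjusted p = 0.317). Of 13 calcium channel genes, 1 rose (2 without P6 litter 4) and 7 fell, including Cacna1g (-1.31), Cacna1e (-0.95) and Cacna1b (-0.93), and the list was called lower (adjusted p = 0.000683, but adjusted p = 0.509 with an estimated correlation). Of the 9 principal neuron and glycinergic genes 4 rose and 2 fell, the list being called higher (adjusted p = 0.0026, and adjusted p = 0.334 with an estimated correlation). Its other large members were Slc6a5, which rose by 1.05, and the transcription factor Foxp1, which fell by 1.05. Of 16 active zone genes 2 rose and 6 fell (3 and 9 adjusted over the list alone), with Unc13b at -1.2 and Erc2 at -0.73. Only 1 of them rose without any 1 of P0 litters 1, 4 and 5 or P6 litters 1, 2 and 5, and 3 fell without P0 litter 2 or P6 litter 3. The active zone list was called lower (adjusted p = 0.0271), a call lost with an estimated correlation (adjusted p = 0.72), without P0 litter 2 (adjusted p = 0.0608), P6 litter 3 (adjusted p = 0.0568) or P6 litter 4 (adjusted p = 0.0894), and without the 3 arrays of low weight (adjusted p = 0.0638). Of 10 genes of the node of Ranvier and paranode 3 rose, and 1 fell without P6 litter 1 or 2 (4 rose and 1 fell adjusted over the list alone), namely the sodium channel Scn1a (1.63), Cntnap1 (1.6) and Nfasc (1.37), and the list was called higher (adjusted p = 0.0116, and adjusted p = 0.491 with an estimated correlation).

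Other neuronal groups held members that moved in both directions over this week and were not called as lists. Of 23 potassium channel genes 5 rose and 1 fell (adjusted p = 0.0987), with Kcnab3 at 1.48 and Kcna2 at 1.41. No potassium channel fell without any 1 of P0 litters 1, 3 and 5 or P6 litters 3, 4 and 5. This list was called higher without P6 litter 4 (adjusted p = 0.0392) and without the 3 arrays of low weight (adjusted p = 0.0263). Of 8 sodium channel genes 3 rose and 2 fell (adjusted p = 0.286), with Scn1a at 1.63 and Scn2b at 1.04, and 1 fell without P0 litter 4 and 0 without P6 litter 4. Of 13 ionotropic glutamate receptor genes 3 rose and 5 fell (adjusted p = 0.924), the AMPA receptor subunit Gria3 rising by 2.72, the kainate receptor subunit Grik2 rising by 1.29 and the NMDA receptor subunit Grin2b falling by 1.39. Of 30 synaptic vesicle and release genes 6 rose and 5 fell (8 and 6 adjusted over the list alone; adjusted p = 0.825), with Syt2 at 1.38, the syntaxin Stx1a at -1.2 and Syt4 at -1.19. For the glutamate receptor list the median was below 0 and the mean above it, and for the vesicle list the median and test pointed up while the mean was below 0.

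Genes of neurite growth and immature neurons fell together from P0 to P6. Of 23 measured members 19 fell and 0 rose, and the list was called lower (adjusted p = 6.53e-17, against adjusted p = 0.0576 with an estimated correlation). Besides Dcx they included Dpysl5 (-1.69), Dpysl3 (-1.6) and the microtubule-associated protein tau, Mapt (-1.62). Axon guidance genes went both ways, with 9 of 40 higher and 11 lower (10 and 12 adjusted over the list alone; adjusted p = 0.53). The semaphorins Sema5a (1.97) and Sema4d (1.57) and the ephrin receptor Epha6 (1.75) rose, and the netrin receptor Dcc fell by 1.26. Of 31 genes of BMP and TGF-beta signalling 4 rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.346), with Bmp5 at 2.8, Bmp4 at 1.59 and Tgfb3 at -1.61, and 4 fell without P0 litter 3. Of 24 genes of the extracellular matrix and perineuronal nets 10 rose and 3 fell (11 and 5 adjusted over the list alone), with Tnr at 2.7, the link protein Hapln4 at 2.41 and Lgi1 at 1.35 beside Tnc at -2.95. That list was called higher (adjusted p = 0.000144, but adjusted p = 0.439 with an estimated correlation). Of 28 cell cycle genes 5 fell and 0 rose, among them Mcm4 (-0.48), Kif23 (-0.45), Mcm6 (-0.43) and Mcm3 (-0.41). The count was 2 without any 1 of P0 litters 3 and 4 or P6 litters 3 and 5, and 3 without any 1 of P0 litters 1, 2 and 5 or P6 litter 4. The list was called lower (adjusted p = 0.0176). The cell cycle call was lost with an estimated correlation (adjusted p = 0.72), without P0 litter 3 (adjusted p = 0.0727) or P6 litter 4 (adjusted p = 0.0843), and without the 3 arrays of low weight (adjusted p = 0.0681).

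Many markers of glia rose over the same week. Of 17 myelin genes 15 rose (16 adjusted over the list alone; camera adjusted p = 1.04e-41, and adjusted p = 3.06e-05 with an estimated correlation), and Gjb1 (0.41) and Opalin (0.18) did not pass. All 11 measured oligodendrocyte precursor genes had positive changes and 9 rose (11 adjusted over the list alone; adjusted p = 2.55e-13, and adjusted p = 0.00119 with an estimated correlation), led by Enpp6 (2.94) and Gpr17 (2.78), which mark newly forming oligodendrocytes. Of 16 astrocyte genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), among them S100b (3.01) and the connexin Gjb6 (1.35). The astrocyte list was called higher (adjusted p = 2.91e-08, but adjusted p = 0.0752 with an estimated correlation). Of 14 microglial genes 7 rose (8 adjusted over the list alone; adjusted p = 5.61e-06, and adjusted p = 0.00691 with an estimated correlation), including Ctss (1.95), Tyrobp (1.67) and Laptm5 (1.15). Of 11 complement and antigen presentation genes only B2m rose (1.25), and 2 rose without P0 litter 4. This list's call (adjusted p = 0.0271) was lost with an estimated correlation (adjusted p = 0.173), without P0 litter 1 (adjusted p = 0.053), P0 litter 3 (adjusted p = 0.0844) or P6 litter 4 (adjusted p = 0.065), and with quantile normalization (adjusted p = 0.0592).

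Few markers of other cell types passed between P0 and P6, and no list of vascular, meningeal, erythroid, ependymal or other neuronal markers was called. Of 14 endothelial genes 2 rose, Ptprb (0.77) and Slco1a4 (0.73; list adjusted p = 0.321). Of 11 pericyte and smooth muscle genes 1 rose, Rgs5 (1.06), and 1 fell, Tagln (-0.36; adjusted p = 0.733). None of them fell without any 1 of P0 litters 1, 2, 4 and 5 or P6 litters 1, 2, 3 and 5, and 2 rose without P6 litter 3. No meningeal fibroblast gene of 12 (adjusted p = 0.686), no erythroid gene of 5 (adjusted p = 0.486) and no ependymal or choroid plexus gene of 8 (adjusted p = 0.775) passed in limma, but 1 meningeal gene fell without P0 litter 5 and 1 erythroid gene rose without P6 litter 1. Of 12 glutamatergic neuron genes 3 fell and 0 rose (0 and 4 adjusted over the list alone; adjusted p = 0.152), namely Slc17a8, Neurod6 (-1.34) and Nfix (-0.64), although the list's median was above 0, and the list was called lower once dim probe sets were dropped (adjusted p = 0.0317). Of 8 genes of motor and cholinergic neurons 1 rose, the choline transporter Slc5a7 (0.72; adjusted p = 0.549), and of 8 genes of serotonergic neurons 1 rose, Ddc (2.08; adjusted p = 0.187). Of 19 collagen and laminin genes 2 rose (adjusted p = 0.727), the list's median lying below 0 and its mean above, and 1 fell without P0 litter 4 or 5 or P6 litter 5. Among metabolic genes, 1 of 17 in cholesterol synthesis rose, Ebp (1.02; adjusted p = 0.317), and 2 of 13 in glycolysis and lactate handling rose and 1 fell, with the lactate transporter Slc16a1 at 1.26 and Aldoc at 0.7 (adjusted p = 0.189, or adjusted p = 0.0426 without the 3 arrays of low weight). No mitochondrial respiration gene of 18 passed, 4 rose without P0 litter 3, and Ndufb8 at 0.49 had the widest change. The mitochondrial list was not called (adjusted p = 0.0745) but was called higher with litter as a block (adjusted p = 0.0321), after quantile normalization (adjusted p = 0.0386), without P0 litter 3 (adjusted p = 0.00615), without P6 litter 4 (adjusted p = 0.029) and without the 3 arrays of low weight (adjusted p = 0.0253). Of 18 immediate-early and heat-shock genes, which respond to handling of tissue, 4 rose, among them Fosl2 (0.97) and Jun (0.8; list adjusted p = 0.0972).

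**Figure D2:**
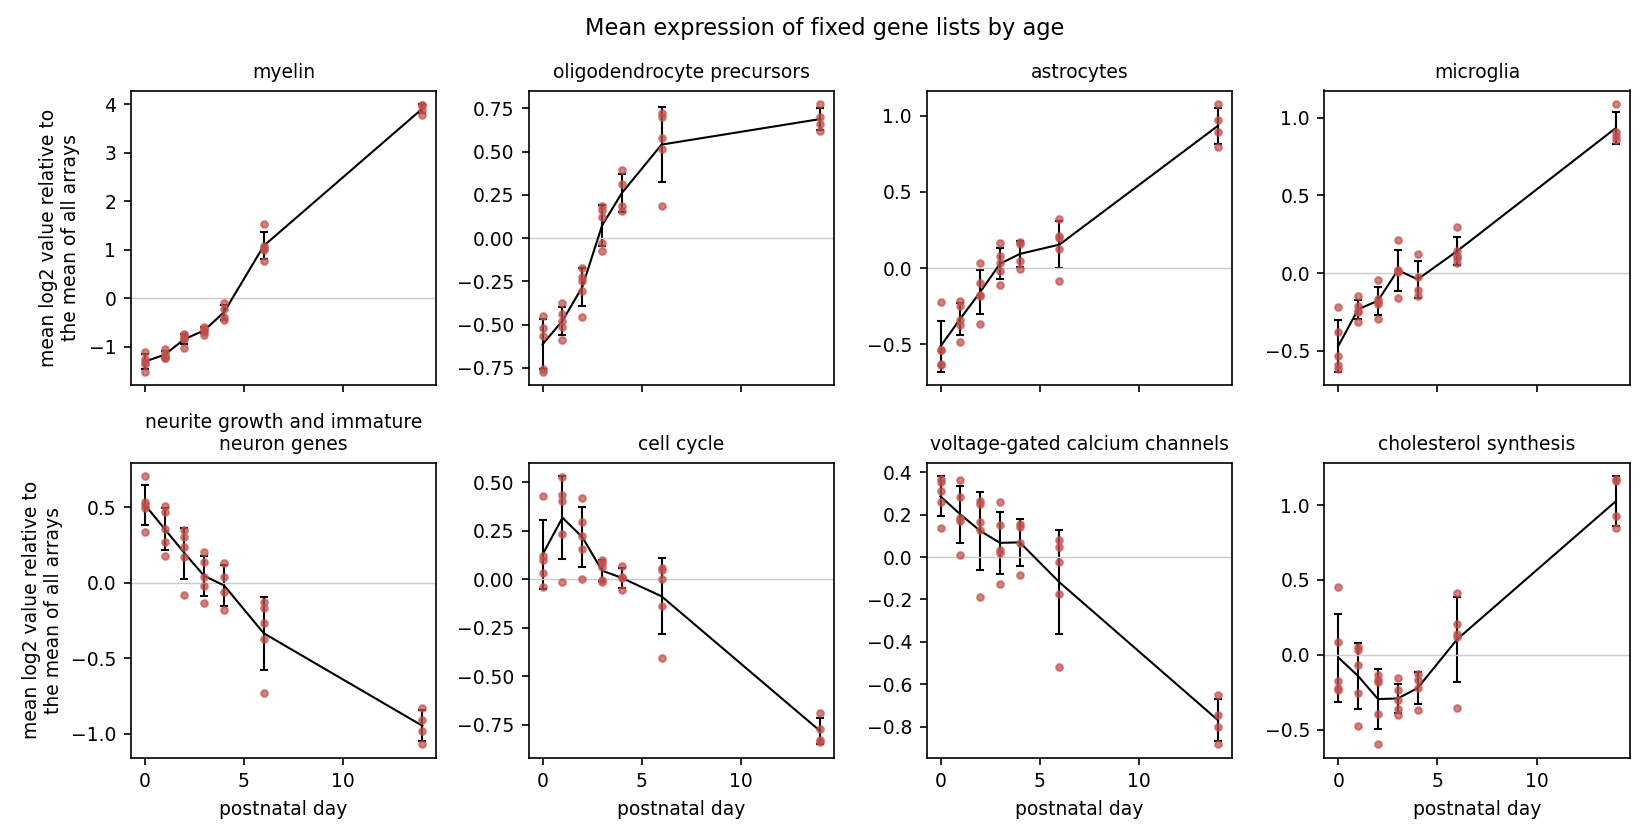
Mean log2 level of the members of selected gene lists at each postnatal age, each member taken relative to its mean over all 33 arrays, with a point for each mouse, lines through the age means and error bars of SD. The myelin mean goes from -1.31 at P0 to 1.08 at P6 and 3.91 at P14, with a wider change after P6 than before it.

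Within the first week, few genes passed in any single-day step. From P0 to P1 Calb1 rose by 2.25 ± 0.191 (adjusted p = 1.99e-08, 5 mice against 5) and Slc17a8 fell by 1.24 ± 0.215 (adjusted p = 0.00604). Mitf (1.08), Gabra2 (1.07) and Luzp2 (0.89) also rose, and Efna2 (-0.87), Pla2g3 (-0.7) and Psd (-0.42) fell. From P1 to P2 the oligodendrocyte gene Bcas1 rose by 1.02 ± 0.131 (adjusted p = 0.000211) and Mbp by 0.74 ± 0.127 (adjusted p = 0.0154). From P2 to P3 Htra1 (1.06), Gpr37l1 (0.89), Mbp (0.85) and Hapln4 (0.78) rose, and from P3 to P4 the myelin genes Mobp (1.27 ± 0.17; adjusted p = 0.000493) and Mag (1.03 ± 0.182; adjusted p = 0.0292). Counts in limma were 26 higher and 8 lower for P1 against P0, 3 and 0 for P2 against P1, 4 and 0 for P3 against P2 and 2 and 0 for P4 against P3, with 1462, 575, 587 and 483 probe sets at an unadjusted p under 0.05. With litter as a block the first 3 of these became 50 and 13, 8 and 1, and 8 and 1. In limma fits of only the 2 ages compared, 1 rose and 0 fell for P1 against P0, and no probe set passed in the next 3 steps. Leaving out single mice moved the P1 count of higher probe sets between 11 (without P1 litter 2) and 104 (without P0 litter 3) and that of lower ones between 2 (without P1 litter 1) and 10 (without P0 litter 5). Higher ones numbered 16, 13 and 17 without P0 litters 2, 4 and 5 and 15 and 14 without P1 litters 1 and 3. Lower ones numbered 5 and 3 without P0 litters 2 and 4 and 3 and 4 without P1 litters 2 and 3. The P3 count of higher probe sets lay between 2 (without P2 litter 4) and 7 (without P3 litter 2), and the P4 count was 1 without any 1 of P3 litters 1 to 4 or P4 litters 1, 3 and 5. Quantile normalization moved the P1 split from 76.5% to 61% higher, with 50 higher and 32 lower, and that of P3 against P2 to 70% higher, with 7 and 3. Centring gave 85.7% higher for P3 against P2, with 6 and 1.

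Many of these calls were lost in fits without single mice, which have fewer mice, often with a change of similar size. The call of Mitf was lost without P0 litter 4 (1.00), P0 litter 5 (0.94) or P1 litter 1 (0.95), and that of Gabra2 without P1 litter 2 (0.99). Efna2 lost its call without P0 litter 1 (-0.81), P1 litter 1 (-0.79) or P1 litter 2 (-0.84). Pla2g3 did so without P0 litter 2 (-0.67), P0 litter 4 (-0.68), P1 litter 1 (-0.61) or P1 litter 3 (-0.70). Psd passed only without P0 litter 2, P0 litter 3 or P1 litter 4 among the single omissions, its values otherwise lying between -0.42 and -0.38. The P2 rise of Mbp lost its call without P1 litters 1 (0.70), 3 (0.67) or 5 (0.68) or P2 litters 3 (0.67) or 5 (0.73). Htra1 lost its call without P2 litter 2 (1.02), P2 litter 4 (0.96) or P3 litter 5 (0.99), and Hapln4 without P2 litter 4 (0.68), P3 litter 3 (0.74) or P3 litter 4 (0.73). The P4 rise of Mag kept its call among single omissions only without P3 litter 5 or P4 litter 2, with values from 0.87 to 1.07 elsewhere. Pvalb was not called in the first 3 steps (0.87, 0.94 and 1.01; adjusted p = 0.068, 0.136 and 0.0716) and was called in each with litter as a block, and Calb1 likewise from P1 to P2 (0.98; adjusted p = 0.0712).

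The myelin list was called higher in 3 of these 4 steps, in which 1, 1 and 2 of its 17 genes passed (5, 3 and 7 adjusted over the list alone). Its mean change was 0.322 from P1 to P2 (adjusted p = 4.76e-15, and adjusted p = 0.00956 with an estimated correlation), 0.18, with a median of 0.0313, from P2 to P3 (adjusted p = 0.000543, but adjusted p = 0.354 with an estimated correlation) and 0.376 from P3 to P4 (adjusted p = 5.08e-15, and adjusted p = 0.00956 with an estimated correlation). Oligodendrocyte precursor genes were called higher from P2 to P3 (mean change 0.356; adjusted p = 2.51e-09, and adjusted p = 0.00691 with an estimated correlation). The neurite growth list was called lower from P0 to P1 (adjusted p = 0.00204), P1 to P2 (adjusted p = 0.000217) and P2 to P3 (adjusted p = 1.93e-05), calls that were lost with an estimated correlation (adjusted p = 0.607, 0.509 and 0.439). None of the other list calls of these 4 steps held with an estimated correlation.

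From P4 to P6 myelin genes rose further. Mobp rose by 3.59 ± 0.17 (adjusted p = 2.03e-15, 4 mice against 5), or 12-fold, Ermn by 3.02 ± 0.136 (adjusted p = 9.21e-16), Mog by 2.88 ± 0.237 (adjusted p = 2.05e-09) and Mag by 2.4 ± 0.182 (adjusted p = 3.51e-10). Of 17 myelin genes 11 rose (14 adjusted over the list alone; camera adjusted p = 1.28e-68, and adjusted p = 5.85e-07 with an estimated correlation). Pvalb rose by 1.28 (adjusted p = 0.000805). The largest falls were those of Stc1 (-1.01), Stk32b (-0.95), Khdrbs2 (-0.82) and Cnih2 (-0.78). Stk32b lost its call without P4 litter 2 (-0.90) or P4 litter 3 (-0.89), and Cnih2 without P4 litter 3 (-0.69). The glycine receptor subunit Glra1 changed by 1.11 without passing (adjusted p = 0.0608). Gria3 (0.91) and Calb1 (0.70) were not called and were called with litter as a block (1.01 and 0.79). Lists of neurite growth (adjusted p = 7.33e-11) and cholesterol synthesis (adjusted p = 3.66e-08) were called lower and higher, without a member passing over all probe sets and with 6 lower and 4 higher adjusted over the list alone. Both list calls were lost with an estimated correlation (adjusted p = 0.153 and 0.204). In all, 70 probe sets rose and 10 fell, or 98 and 18 with litter as a block, and without P4 litter 3 only 4 fell. The counts were 133 and 36 after quantile normalization, 130 and 28 with array quality weights, and 25 and 3 in a fit of only these 2 ages, and 19 fell after centring.

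From P6 to P14 the largest rises included many myelin genes and the astrocyte gene Gfap, and the largest falls included genes of calcium, sodium and nicotinic channels and of vesicle release. Opalin rose by 5.12 ± 0.128 (5 mice against 4; adjusted p = 5.21e-23), Mal by 4.83 ± 0.139 (adjusted p = 1.41e-21) and the G protein subunit Gng8 by 4.83 ± 0.246 (adjusted p = 1.79e-15). The astrocyte filament gene Gfap rose by 4.32 ± 0.196 (adjusted p = 8.08e-17), followed by Ermn (4.31), Gjb1 (4.27), Trf (4.09) and Apod (3.8). The calcium channel subunit Cacna1e fell by 3.32 ± 0.173 (adjusted p = 2.9e-15), and Syt1 fell by 3.22 ± 0.134 (adjusted p = 9.58e-18), or 9.29-fold. Rgs8 (-2.94), the sodium channel subunit Scn3b (-2.92), Syt17 (-2.72), the nicotinic receptor subunit Chrna5 (-2.64), Tex47 (-2.54) and Crabp1 (-2.51) fell next. These 16 genes were chosen among called probe sets whose P6 and P14 mice do not overlap, which held for 2633 of the 3485 calls. By chance this would hold for 1.59% of all probe sets, but again the shares are not comparable. Opalin (3.8), Gng8 (4.09), Gfap (4.83) and Gjb1 (4.18) at P6 and Cacna1e (4.75), Scn3b (4.66), Chrna5 (3.45), Tex47 (4.4) and Crabp1 (4.99) at P14 had means under the median of their arrays, which averaged 4.953 and 5.069, so no fold is given for them and their order is uncertain. In all, 2627 probe sets rose and 858 fell (75.4% higher), 615 and 202 of them by at least 2-fold. The split depended on scaling: it was 1827 higher and 1740 lower after quantile normalization (51.2% higher) and 1977 and 1441 after centring (57.8% higher). Centring each array moved the median change of all probe sets from 0.054 to -0.0622, a shift of 0.116, and the changes given for this comparison are on the deposited scale.

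Between P6 and P14, channel and receptor genes of the same family moved in opposite directions. Of 13 calcium channel genes 1 rose and 7 fell (1 and 8 adjusted over the list alone), with Cacna1g (-1.34) and Cacna1h (-1.09) beside Cacna1e and with Cacnb4 higher by 0.7. The list was called lower (adjusted p = 1.41e-07), a call lost with an estimated correlation (adjusted p = 0.238). Of 14 inhibitory receptor and chloride transporter genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.733), and 2 fell without any 1 of P6 litters 2 and 5 or P14 litter 2. Glra1 rose by 3.6 ± 0.272 (adjusted p = 1.22e-11), or 12.1-fold, the chloride transporter Slc12a2 rose by 1.48, and the GABA-A receptor subunits Gabra3 (-1.64) and Gabra5 (-1.29) fell. Glra2 fell by 0.71 (adjusted p = 0.0392), a call lost with litter as a block (-0.69), without any 1 mouse of P14 (values from -0.74 to -0.66) and without P6 litters 2 (-0.72), 3 (-0.71), 4 (-0.68) or 5 (-0.65). Of 13 ionotropic glutamate receptor genes 4 rose and 4 fell (4 and 6 adjusted over the list alone), with Gria1 (-1.89), Grin2b (-1.6) and Grin2a (-1.33) lower and Gria3 higher by 1.27. That list was not called (adjusted p = 0.0824) but was called lower with litter as a block (adjusted p = 0.0231), without P14 litter 2 (adjusted p = 0.0467) and without P6 litter 4 (adjusted p = 0.0161). Of 23 potassium channel genes 7 rose and 6 fell (adjusted p = 0.365), with the beta subunits Kcnab2 (1.91) and Kcnab1 (1.43) higher and Kcnh5 at -1.6. Of 8 sodium channel genes 2 rose and 2 fell (adjusted p = 0.565), with Scn4b at 1.84 beside Scn3b at -2.92 and Scn3a at -1.66. Of 10 node and paranode genes 3 rose, Cntn2 (1.14), Scn8a (0.85) and Nfasc (0.71; adjusted p = 0.178).

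Principal neuron genes went both ways in this interval, with 5 of 9 higher and 3 lower (adjusted p = 0.895), or 3 higher without P6 litter 4 or P14 litter 1. Kcna1 rose by 1.34 and Pvalb by 1.07, while Foxp1 fell by 1.17 and Kcnc1 fell by 1.16. The fall of Kcnc1 was not called on the mean of its probe sets (-0.38). Slc6a5 rose by 0.38 (adjusted p = 0.0165), a call lost after quantile normalization (0.23), after centring (0.26), without P6 litter 4 (0.28) and without P14 litter 1 (0.34). The rise of Syt2 (0.58; adjusted p = 0.0235) was lost after quantile normalization (0.33), without P14 litters 1 (0.54) or 3 (0.51) and without P6 litters 3 (0.52) or 4 (0.45). Of 30 synaptic vesicle and release genes 9 rose and 4 fell (10 and 5 adjusted over the list alone; adjusted p = 0.899), with Rab3c (-2.04) and Vamp2 (-0.81) lower beside Syt1 and Rph3a higher by 0.84. Of 16 active zone genes 1 rose and 5 fell (1 and 7 adjusted over the list alone), with Ppfia2 (-1.74) and Erc1 (-1.37) lower and Ptprd higher by 1.51, and 8 fell without P6 litter 4. This list was called lower (adjusted p = 0.000153, but adjusted p = 0.432 with an estimated correlation). The median and mean of the principal neuron list and of the inhibitory receptor list were above 0 while camera, which compares a list with all other genes, pointed down.

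Many genes of neurite growth and of cell division fell from P6 to P14. Of 23 neurite growth genes 14 fell and 2 rose, or 1 rose without P14 litter 2 (adjusted p = 9.62e-12, but adjusted p = 0.137 with an estimated correlation), including L1cam (-2.3), Gap43 (-1.71), Dcx (-1.68) and Dpysl3 (-1.61). Of 28 cell cycle genes 16 fell and 0 rose (18 fell adjusted over the list alone), with the proliferation marker Mki67 at -1.9, Top2a at -1.67, Prc1 at -1.39 and Mcm6 at -1.35. The cell cycle list was called lower (adjusted p = 2.88e-15, and adjusted p = 0.0575 with an estimated correlation). Axon guidance genes split into 7 higher and 7 lower of 40 (8 and 8 adjusted over the list alone), with Dcc (-2.3), the slit receptor Robo2 (-2.27) and Sema3a (-1.95) lower and Efnb3 higher by 1.37. That list was not called (adjusted p = 0.107), but was called lower with litter as a block (adjusted p = 0.0417), after quantile normalization (adjusted p = 0.0471) and without P6 litter 4 (adjusted p = 0.0352). Of 31 BMP and TGF-beta genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.875), with Id3 at 1.43 and Smad9 at 1.09. Of 24 matrix and perineuronal net genes 7 rose and 2 fell (adjusted p = 0.827), with Lgi3 at 2.13 and Hapln1 at -0.9. The median of the matrix list was 0.0396 as deposited and turned negative after quantile normalization (-0.0298) and centring (-0.0766).

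Many myelin, astrocyte, microglial and vascular markers rose from P6 to P14. All 17 myelin genes rose (adjusted p = 1.58e-33, and adjusted p = 0.000127 with an estimated correlation). Of 11 oligodendrocyte precursor genes 4 rose and 1 fell (adjusted p = 0.718), Enpp6 by 0.93 and the precursor receptor Pdgfra by -0.92. Of 16 astrocyte genes 9 rose and 1 fell, with S100b (1.77), Gjb6 (1.75) and Ntsr2 (1.59) behind Gfap. None of them fell without any 1 of P6 litters 1, 2, 3 and 5 or P14 litters 1, 3 and 5, and 2 fell without P6 litter 4. The astrocyte list was called higher (adjusted p = 0.00174, but adjusted p = 0.423 with an estimated correlation). Of 14 microglial genes 12 rose (13 adjusted over the list alone; adjusted p = 3.47e-06, and adjusted p = 0.00691 with an estimated correlation), among them Csf1r (1.42), Tyrobp (1.36) and Ctss (1.18). Of 14 endothelial genes 9 rose (12 adjusted over the list alone), including the transporters Slco1a4 (1.55) and Slc2a1 (1.55) and the receptor Flt1 (1.28). The endothelial list was called higher (adjusted p = 1.95e-05, and adjusted p = 0.0724 with an estimated correlation). Of 11 pericyte and smooth muscle genes 7 rose (8 adjusted over the list alone), with Vtn at 1.47 and Acta2 at 1.42 (adjusted p = 0.0099, but adjusted p = 0.114 with an estimated correlation). Of 12 meningeal fibroblast genes 5 rose, led by Dcn (1.29; adjusted p = 0.135), and of 11 complement and antigen presentation genes 4 rose (5 adjusted over the list alone; adjusted p = 0.159), with C1qa at 0.99.

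Many genes of cholesterol synthesis rose from P6 to P14, and the lists of glycolysis and of mitochondrial respiration were not called. Of 17 cholesterol synthesis genes 11 rose and 0 fell (15 and 0 adjusted over the list alone), including Ebp (1.61), Sc5d (1.54), Lss (1.51) and Msmo1 (1.44). The list was called higher (adjusted p = 4.59e-07, but adjusted p = 0.262 with an estimated correlation), beside the rise of the myelin list. Of 13 glycolysis and lactate genes 6 rose and 1 fell, with Slc2a1 at 1.55, Slc16a1 at 1.21 and Aldoc at 0.86. That list was not called (adjusted p = 0.0563) but was called higher after centring (adjusted p = 0.0231) and without P14 litter 3 (adjusted p = 0.0374), P14 litter 5 (adjusted p = 0.0499), P6 litter 1 (adjusted p = 0.0428) or P6 litter 2 (adjusted p = 0.0286). Of 18 mitochondrial respiration genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.154), with Ogdh at 0.98 and Sdha at 0.63, and the split was 2 and 2 after quantile normalization. The count of rises was 2 without P14 litter 1, 3 without P14 litter 5, and 4 without any 1 of P6 litters 2 and 4 or P14 litter 3. Of 18 immediate-early and heat-shock genes 10 rose and 0 fell (12 and 1 adjusted over the list alone), with Btg2 (1.19), Dusp1 (1) and Hsph1 (0.94), or 6 higher without P6 litter 4 and 1 lower without P14 litter 3, and the list was called higher (adjusted p = 0.0099, but adjusted p = 0.273 with an estimated correlation). Of 19 collagen and laminin genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.438), with Lama2 at 0.97, and 0 fell without P14 litter 1. Among the remaining cell types, 1 of 5 erythroid genes (Fech, 0.54; adjusted p = 0.653) and 1 of 8 ependymal and choroid plexus genes rose (2 adjusted over the list alone; adjusted p = 0.684). Of 12 glutamatergic neuron genes 1 fell (none adjusted over the list alone; adjusted p = 0.807), of 8 motor and cholinergic genes 1 fell, Prph (-0.9; 2 fell adjusted over the list alone; adjusted p = 0.249), and of 8 serotonergic genes 2 rose, with Ddc at 0.75 (adjusted p = 0.855). The ependymal count was 0 without any 1 of P6 litters 1, 2, 4 and 5 or P14 litters 3 and 5, and 2 without P6 litter 3 or P14 litter 2. The glutamatergic fall was lost without any 1 of P6 litters 1, 3 and 5 or P14 litters 1, 2 and 5, with 1 rise without P14 litter 1 or 5. The motor count was 2 without P6 litter 4 or 5, and the serotonergic count 1 without any 1 of P6 litters 2 and 3 or P14 litters 1, 3 and 5.

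Most genes called both before and after P6 kept their direction. Of the probe sets called in both main comparisons, 562 rose in both and 284 fell in both, while 84 rose and then fell and 104 fell and then rose. After quantile normalization 165 rose and then fell and 562 fell in both, and after centring 455 fell in both. Independent lists of the same sizes as deposited would share 169, 68.2, 55.1 and 209. The comparisons share the P6 mice, and 100 simulations of unchanged groups, in which few genes are called at all, gave 0 in each class. With P6 litters 1 and 2 used for the first comparison and litters 3 to 5 for the second, the counts were 512 and 124 for the same direction and 46 and 14 for opposite directions. With the litters exchanged they were 286 and 283, and 55 and 40. Leaving out P0 litter 3, P6 litter 3 or P6 litter 4 moved the count that fell and then rose to 65, 66 and 42. Among the genes that rose and then fell, the small muscle protein gene Smpx had means of 4.51, 8.03 and 5.96 at P0, P6 and P14, Hrc 4.67, 6.13 and 4.76, Mlip 5.12, 7.59 and 6.24, Gipc2 4.99, 6.27 and 4.39 and Rrad 3.68, 4.77 and 3.69. Among those that fell and then rose, Psd2 had means of 7.57, 6.18 and 7.4, Dact1 7.38, 5.13 and 6.1, Nkd1 5.88, 5.01 and 6.55, Nrbp2 6.4, 5.54 and 6.49 and the stathmin Stmn4 9.07, 8.26 and 9.55.

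Arrays of the same age differed from each other along a shared axis that the ages do not account for. The leading component of the residuals from the age means held 24.9% of their variance. Its scores followed the spread of values on each array, taken as the SD over probe sets minus the mean of its age (Pearson's r = 0.984, permutation p = 1e-05; Spearman's rho = 0.968, permutation p = 1e-05; 33 arrays, both p being the smallest the permutations can give). Without the 2 arrays farthest from the median spread r was 0.976. Both quantities come from the same values, and the sign of the component was set so that r is positive. The relation therefore describes the axis and does not test a cause. Within litters 1, 2, 3 and 5, of 7 arrays each, r was 0.969, 0.991, 0.985 and 0.981 (exact permutation p = 0.0014, 2e-04, 0.00099 and 0.00079), and none was computed for litter 4, which has 5 arrays. This was the only relation of its kind computed, and no batch other than litter is given by the labels. The arrays of litter 4 at P1, P2 and P6 had quality weights of 0.45, 0.432 and 0.271, and were the only arrays with a weight under 0.5.

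**Figure D3:**
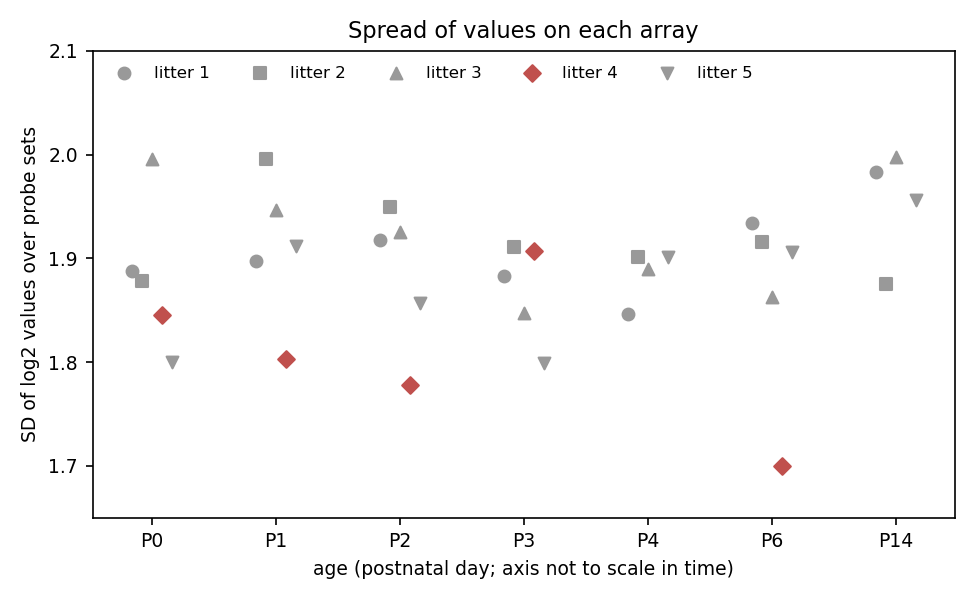
SD of log2 values over probe sets on each array (vertical axis, log2) by age (horizontal axis, not to scale in time), with a point for each of the 33 arrays and a marker shape for each litter. The arrays of P1, P2 and P6 from litter 4 have the lowest SD of their ages (1.803, 1.778 and 1.7).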

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

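The tests of a narrow spread and of litter 4 as a whole were chosen only after the arrays' weights had been seen, and the check of age labels on single genes after the closest ages had been. Values below are those of a mouse whose gap to its nearest neighbour was large against the range of its age, by Dixon's criterion. Of 374 groups of mice examined 24 (6.42%) met it, and chance alone gives about 1 in 20.

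Several of these values belong to mice of litter 4. At P6 the litter 4 mouse had the lowest log2 value of Cacna1e (7.51, the next being 8.13) and Dcx (7.45, next 8.03). It also had the lowest mean over the members of a list, each taken relative to its mean over all arrays, for principal neuron genes (0.15, next 0.47), potassium channels (-0.229, next 0.087) and glutamate receptors (-0.416, next 0.087). At P2 it was lowest for Hapln4 (4.68, next 5.14), Slc6a5 (10.1, next 10.4) and Slc12a5 (5.94, next 6.93). At P1 it was lowest for Dcx (9.71, next 10.3) and highest for Glra1 (5.11, next 4.06), and at P0 highest for Nrbp2 (6.8, next 6.34).

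The first pattern is the low array weight of litter 4 at P1 (0.45), P2 (0.432) and P6 (0.271). A difference of litter 4 as a whole would put its array lowest on the residual component at all 5 of its ages, and it was lowest at 3, although residuals within this litter had the highest mean correlation of the 5 litters (0.2). Labels wrong by more than 1 age are argued against, since each array's closest age mean was at most 1 age from its own (P0 for P1 litter 4, P1 for P2 litter 4). An exchange of labels with a neighbouring age could give the same closest ages for P1 and P2 litter 4, so it stays open. Some genes of these steps lay outside the range of the earlier age. Examples are Calb1 (6.63) and Slc17a8 (6.24) at P1 litter 4 against 4.13 to 5.14 and 7.51 to 8.55 at P0, and Bcas1 (7.25) and Mbp (5.71) at P2 litter 4 against 5.74 to 6.59 and 4.76 to 5.5 at P1. Others lay within it, such as Kitl (4.91 against 4.16 to 5.31) and Hmmr (4.61 against 4.41 to 5.24) at P1 litter 4. All 40 probe sets called for P1 against P0 without P1 litter 4 do not decide on such an exchange, as this mouse lay past all P0 mice for 26 (65%). Other P1 mice did so for 82.4% to 100% of such probe sets. P0 mice did so for 25% to 51.9%, except P0 litter 3 with 80.5%. That P0 mouse scored -16.9 on the first component, where P1 averaged -18.63, and closest age means were computed only for the 3 arrays of low weight. A narrower spread of values on some arrays is a candidate explanation that stays open. The component followed the array spread at r = 0.984 over all arrays, and these 3 lie at its low end, but both come from the same values, so this does not test it. RNA quality per mouse is not given and no biological explanation was tested.

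The second pattern is the presence of genes known from muscle, Smpx, Hrc, Mlip and Rrad, among those that rose to P6 and fell by P14. Skeletal or cardiac muscle in the P6 samples is argued against by 17 measured muscle transcripts, whose median log2 change from P0 to P6 was -0.0055 with 0 higher and 1 lower in limma. The means of abundant muscle transcripts at P0 and P6 were 4.76 and 4.35 (Acta1), 5.17 and 5.21 (Ckm) and 4.02 and 4.15 (Mylpf). A single unusual P6 mouse is argued against as well, since 0 of the named genes lost their P6 call when any 1 of the 5 P6 arrays was left out. A transient expression in cells of this nucleus, tied to age, may account for the pattern and stays open as an untested hypothesis.

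The third pattern is the set of neuronal genes among the largest falls from P6 to P14, such as Cacna1e, Syt1 and Scn3b, beside the rise of glial markers. Dilution of neuronal RNA by glial RNA would, with no change within neurons, lower all neuronal genes alike. That is argued against by 25 measured pan-neuronal genes, whose median log2 change was 0.36 (quartiles 0.11 and 0.575). Of these 9 were higher and 3 lower, namely Rbfox3 (-1.02), Rtn1 (-0.5) and Map2 (-0.28). The median was 0.144 after quantile normalization (quartiles -0.0107 and 0.342, with 8 higher and 4 lower), 0.244 after centring and 0.263 without the 3 arrays. A rise within neurons could offset dilution, so the list cannot decide whether dilution has a part in the falls, and that stays open. A different reading of bright probe sets at P14 was examined too, and 0 of the 8 named falls lost their call after quantile normalization, Syt1 changing by -3.43 there. These genes were picked as the largest falls, and centring shifted the median change by only 0.116. Their calls could therefore hardly be lost, so this test does not decide and the explanation stays open. A change with age in the neurons themselves may account for these falls, and a change in the share of neuron types in the dissected tissue stays open and was not tested.

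The remaining values are given without explanation. At P6 the litter 1 mouse was highest for Ermn (7.46, next 6.62) and Mog (8.68, next 8). At P14 the litter 2 mouse was highest for Syt1 (8.32, next 7.44), Grin2a (5.93, next 5.61) and Slc17a7 (5.66, next 3.99) and lowest for Glra1 (8.71, next 9.4). At P1 the litter 1 mouse was highest for Kcna1 (6.21, next 5.54), and at P4 the litter 3 mouse was highest for Kcnc1 (7.26, next 6.4). At P0 the litter 3 mouse had the highest list mean for axon guidance (0.198, next 0.0244), extracellular matrix (0.052, next -0.256) and astrocytes (-0.226, next -0.538). At P14 the litter 5 mouse had the lowest list mean for collagens and laminins (0.0674, next 0.217), and the litter 1 mouse the highest for glycolysis (0.724, next 0.516).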

How the results depend on the processing

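The fits without the 3 arrays of weight under 0.5 and with array spread as a covariate were chosen only after the data had been seen. No gene or list result was reversed under any alternative run. The F test count stayed within 1.5 times of 4761 under every alternative. Of 418 gene results, quantile normalization left 394 on their side of the threshold, centring 399, litter as a block 411 and the fit of only 2 ages 378. That last fit uses fewer mice and lost 39 calls. Array quality weights lost 1 and gained 13, the spread covariate lost 9 and gained 15, the fit without the 3 arrays lost 7 and gained 10, and the intensity trend lost 2. Of 99 list results an estimated correlation lost 50, quantile normalization lost 2 and gained 2, and litter as a block lost 3 and gained 3. The block changed the calls of Glra2, Pvalb, Calb1 and Gria3 given beside those genes. It also changed those of the extracellular matrix at P1 (adjusted p = 0.0503) and P4 (adjusted p = 0.218) and of glutamate receptors at P4 (adjusted p = 0.184). Among the 418 gene and 99 list results it changed no other call beyond those in the text. Calls gained by list tests outside these 99 are not given. Litter as a random block gives no list value, and fits of 2 ages give no F test. Signal over background limits dim genes, whose changes are compressed, and of simulated changes of 0.5 log2 the single-day steps recovered 39% to 63%. The causes of the moves below were not tested, except that stricter thresholds lower counts by construction.

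Counts that moved by over 1.5 times were as follows, as higher and lower probe sets. With litter as a fixed block, P1 against P0 gave 50 and 13, P2 against P1 8 and 1, P3 against P2 8 and 1, and P6 against P4 18 lower. As a random block, litter gave 44 higher at P1, 5 higher at P2 and 19 lower at P6 against P4. Quantile normalization gave 50 and 32 at P1, 14 and 1 at P2, 7 and 3 at P3, 133 and 36 for P6 against P4, 1740 lower at P14, and 165 genes that rose then fell and 562 that fell in both. Centring gave 49 and 18 at P1, 9 and 1 at P2, 1 lower at P3, 19 lower for P6 against P4, 1441 lower at P14 and 455 that fell in both. Array quality weights gave 130 and 20 at P1, 13 and 2 at P2, 1 lower at P3, 130 and 28 for P6 against P4, and 141 that rose then fell. The spread covariate gave 53 and 47 at P1, 20 and 2 at P2, 8 and 2 at P3, 133 and 35 for P6 against P4, 1605 lower at P14, 164 that rose then fell and 518 that fell in both. Without the 3 arrays there were 80 and 14 at P1, 3 lower at P3 and 62 that fell then rose. Dropping dim probe sets left 5 lower at P1. A change of at least 1.5-fold left 4 lower at P1, 1667 and 518 at P14, and 693 and 656 for P6 against P0. An adjusted p under 0.01 left 9 and 2 at P1, 2 higher at P3, 1 higher at P4, 46 and 5 for P6 against P4, 538 lower at P14, and 707 and 752 for P6 against P0. Fits of only the 2 ages gave 1 and 0 at P1, 0 higher at P2, P3 and P4, 25 and 3 for P6 against P4, 859 lower for P6 against P0, and 46 that fell then rose. With P6 litters 1 and 2 in the first comparison, 46 rose then fell, 14 fell then rose and 124 fell in both, and with litters 3 to 5 there, 286 rose in both, 55 rose then fell and 40 fell then rose. With an estimated correlation 9 list tests were called.

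Leaving out 1 mouse at a time gave these ranges. The F test called 4115 to 5005. P1 against P0 gave 11 (without P1 litter 2) to 104 (without P0 litter 3) higher and 2 (without P1 litter 1) to 10 lower. The higher count was also 13 to 17 without P0 litters 2, 4 and 5 or P1 litters 1 and 3, and the lower count 3 to 5 without P0 litters 2 and 4 or P1 litters 2 and 3. P2 against P1 gave 2 to 4 higher and 0 lower, P3 against P2 2 (without P2 litter 4) to 7 (without P3 litter 2) higher and 0 lower, and P4 against P3 1 to 2 higher and 0 lower, being 1 without P3 litters 1 to 4 or P4 litters 1, 3 and 5. P6 against P4 gave 47 to 98 higher and 4 (without P4 litter 3) to 13 lower. P14 against P6 gave 2083 to 2687 higher and 699 to 937 lower, and P6 against P0 893 to 1229 higher and 905 to 1419 lower. Genes called on both sides of P6 numbered 463 to 634 (rose in both), 65 to 113 (rose then fell), 42 (without P6 litter 4) to 128 (fell then rose) and 231 to 289 (fell in both). The count that fell then rose was 65 without P0 litter 3 and 66 without P6 litter 3. List tests called numbered 57 to 64. Of 3957 gene results in these fits 162 lost and 17 gained a call, and of 945 list results 47 lost and 10 gained one.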

Other observations

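The test of a constant rate and the 2 added gene lists were chosen after the age comparisons had been seen, though before their own results were, and the count of departures among probe sets with a called slope was chosen after the other results of that test.

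A hypothesis drawn from the age means was that genes changed by a constant amount each day across the first week. A straight line in age fitted with limma to the 29 arrays from P0 to P6 called 2890 probe sets with a slope, 1250 rising and 1640 falling. Pvalb rose by 0.824 ± 0.0315 log2 per day (slope ± SE; adjusted p = 1.71e-18), Mbp by 0.614 ± 0.0214 (adjusted p = 2.46e-19), Kcna2 by 0.239 ± 0.0261 (adjusted p = 3.36e-08) and Syt2 by 0.233 ± 0.0266 (adjusted p = 7.5e-08). Dcx fell by 0.462 ± 0.0251 per day (adjusted p = 7.58e-15), Grin2b fell by 0.234 ± 0.0312 (adjusted p = 1.19e-06) and Gap43 fell by 0.131 ± 0.0143 (adjusted p = 3.19e-08). There were 27 probe sets that departed from a line at an adjusted p under 0.05, 25 of them with a called slope. The number of departures came to 0.934 percent of the number of slope calls, under the 10 percent set beforehand as in favour of a constant rate. They included the myelin genes Mobp (adjusted p = 1.57e-10), Ermn (adjusted p = 1.57e-10) and Mog (adjusted p = 1.09e-05), the dopa decarboxylase gene Ddc (adjusted p = 0.000343) and the apolipoprotein gene Apoe (adjusted p = 0.00114), picked after their values were seen, and the preset genes Calb1 (adjusted p = 1.15e-05) and Slc17a8 (adjusted p = 0.00147). At an unadjusted p under 0.05, 756 of all probe sets departed, where chance gives 834, and 261 (9.03%) of the 2890 with a called slope, where chance gives about 144. A straight line in the measured log2 values is argued against for the 27 probe sets above, and a constant rate stays open for the others. Some of the 27 were dim for part of the week. Mobp at P3 (4.76), Ermn at P4 (3.64) and Slc17a8 at P6 (4.25) had means under the median of their arrays. Changes of dim probe sets are compressed, so for such genes the test cannot tell a changing rate from compression. A departure that misses the threshold does not show a straight line.

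Muscle transcripts and pan-neuronal genes were the 2 lists added. From P6 to P14, 3 of 17 muscle transcripts rose and 0 fell, and from P0 to P6, 9 of 25 pan-neuronal genes rose and 7 fell, with a median of 0.00569.

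Other splits of the mice were used to ask whether the counts of calls can come from chance. For each 2-age comparison 100 splits of the mice were counted, the real one included, and for the F test and the lists 100 regroupings of all arrays. These splits ignore the litters, and what follows on chance holds only over such splits. Chance is argued against for P1 against P0, where 1 split, the real one, gave as many as 34 calls and the highest other gave 10. It is not taken as excluded there, since a fit of only these ages called just 1 probe set. Single omissions also moved the higher count between 11 and 104. Chance can be excluded for P6 against P0 (1 split, 2399 calls, highest other 475) and for the F test (1 regrouping, 4761 calls, highest other 25). The real split alone also reached its count for P2 against P1 (3 calls, highest other 1), P3 against P2 (4 calls, highest other 1) and P4 against P3 (2 calls, highest other 1). Those counts are small and near those of other splits, and no probe set passed there in fits of only the 2 ages. Chance is therefore not taken as excluded for these steps. For the 1034 genes called both before and after P6 the real grouping was the 1 that reached the count, but every other regrouping gave 0, so this adds nothing to the counts of the comparisons themselves. For P14 against P6 the real split alone reached 3485 calls. The highest other, 2646, is the real split with the ages exchanged for all mice except P6 litter 1.

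For P6 against P4, 2 of 100 splits reached the real 80 calls, fewer than the 5 set beforehand as in favour of chance. These splits ignore the litters, and 1 of the 2 gave more calls than the real ages, so chance is not taken as excluded here. That split, with 94 calls, is the real split with the ages exchanged for all mice except P6 litter 4, the mouse of lowest array weight. This split is also 1 of the 16 that part the 4 litter pairs, of which 2 reached 80 calls. In the other 6 comparisons the real split alone, among the 16 that part the pairs, reached its count, the highest other giving 1669 for P14 against P6, 371 for P6 against P0 and at most 1 in the single-day steps. In each of the 7 comparisons these 16 splits are too few for a share under 0.05. With litter as a block P6 against P4 gave 98 higher and 18 lower. For the list tests, 5 of 100 regroupings gave 59 or more calls and the highest gave 66. The median of the other regroupings was 30 of 224 tests. Chance therefore cannot be excluded for that number of calls, and a list call at the preset correlation alone is weak evidence.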
